A study of Mus musculus with 17 samples.

How the data were processed

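RNA-seq libraries from 5 mouse embryonic stem (ES) cell lines were analysed, 17 libraries in all. Per the labels, each line derives from MC1 ES cells (129S6/SvEvTac) and carries the coding sequence of a single transcription factor with a C-terminal His6-FLAG tag at the Rosa26 locus, under a promoter that doxycycline (Dox) holds off. The lines are called iFoxA1, iFoxC1, iFoxG1, iFoxL2 and iFoxP3 after the factor. Cells at 0 h were kept in ES medium with 15% fetal bovine serum, 1000 U/ml leukemia inhibitory factor (LIF) and 0.2 µg/ml Dox. For 24 h of induction, Dox was washed out with washes 3 h apart, and the cells were moved to a differentiation medium with 10% serum. Polyadenylated RNA from 1 µg of total RNA went into strand-specific libraries. No line without a transgene is among the samples.

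The authors quantified transcripts with Salmon 1.4.0 and list DESeq2 1.30.1 and the mm10 build among their tools. They deposited Salmon's estimated counts per transcript, which are not normalised, and a second table of TPM (abundance scaled to transcript length and library total) for the same transcripts. Both deposited tables hold 137271 transcripts. Of these, 137225 were matched by identifier to GENCODE M21, 136349 of them with the same version number. The 46 transcripts without a match held at most 0.0133% of any library's counts and were left out. The annotation behind the deposited tables is not given in the sources used here.

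Estimated counts were summed over the transcripts of each of 53693 genes and rounded to whole numbers. Genes were kept with edgeR's filterByExpr by group, which left 19819. Counts were scaled with TMM factors and fitted with edgeR 4.0.16 (quasi-likelihood, R 4.3.3) in a model with 10 groups, each line at each time. This left 7 residual degrees of freedom. At 0 h, iFoxA1 had 2 libraries and every other line had 1, so the spread was pooled over all groups and the lone libraries were assumed to vary like the others. At 24 h, iFoxA1 had 3 libraries and every other line 2. The contrasts were the change from 0 h to 24 h within each line, the average of these changes with equal weight per line, the difference among the 5 changes (an F test over 4 contrasts), each line's change minus the mean of the 4 others (the line-specific change), each line against the 4 others at 24 h, and the differences among lines at 0 h. The Benjamini-Hochberg adjusted p threshold was 0.05 within each contrast. Fold changes are on the log2 scale with the standard error (SE) derived from the F statistic, and levels are CPM (counts scaled to the TMM-adjusted library total) with the standard deviation (SD) over libraries. The p-values measure the spread between these libraries only, because the labels do not say whether replicates were separate cultures.

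The contrasts, tests, 26 gene lists and most alternatives were chosen before the data were examined. So was the rule for naming genes. For the average change it takes the 12 genes that rose and the 12 that fell most among those past the threshold, with the same sign in all 5 lines and a mean of at least 5 CPM at the higher time. For each line it takes up to 8 that rose and 8 that fell most in the line-specific test among those past the threshold within the line as well, with every 24 h library on the same side of the line's 0 h libraries and the same 5 CPM minimum. Predicted genes and clones without a gene name were passed over, and the transgenes were treated apart. In each list, up to 4 members with the smallest adjusted p may be named. Genes named in the comparisons at 24 h were picked by a rule set only after their values were seen: at most 6 per direction, past the threshold, with the same direction against the other lines in each library set, a mean of at least 5 CPM in the higher group, protein-coding, and a change within the line past the threshold with the same sign.

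Lists were tested with camera (preset correlation 0.01, Benjamini-Hochberg over the lists of a contrast), again with the correlation estimated from the data, and with fry. The lists cover pluripotency, germ layers and extraembryonic tissues, the cell types associated with the 5 factors, 2-cell-like and germ cells, fibroblasts and smooth muscle as other cells the culture could hold, stress, metabolism, the cell cycle, signalling, epithelial junctions, the forkhead family and mitochondrially encoded transcripts.

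Library totals ran from 17.7 to 37.2 M counts, and 15582 to 16928 genes had at least 10 counts in a library. Where a line had 0 counts of a gene at 1 time, the fold change is a lower bound against a floor of 3 counts over the group's libraries. Where it had 1 to 3 counts, the ratio carries a 95% exact counting interval. These floors and intervals cover counting error only. Near-identical gene copies (Pramel6 and Pramel7, Olfr1459, the Usp17l, Tcstv1, Duxf3 and Zscan4 copies) share reads, so a value may belong to a sister copy.

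The fit was tested on simulated data with the same design, the same library sizes and the spread per gene of the main fit. Libraries were drawn independently of each other. The simulation therefore cannot show how a shift shared by several libraries of 1 time affects the calls. With 100 genes changed 2-fold and 100 changed 4-fold, edgeR called 65% and 95% of them for the average change, 5% and 62% within iFoxA1, 0% and 28% within iFoxC1, and 0% and 22% for the line-specific change of iFoxC1. False calls numbered 6, 2, 1 and 0 in the same order. The test of any difference among the 5 lines called 0% of either set when iFoxC1 alone was changed.

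Alternatives were RLE size factors, DESeq2 1.42.0, no low-count filter, replicate number as a block, limma 3.58.1 with trend on log2(TPM + 1) and on log2(TPM + 0.1), only a line's own libraries, a common 0 h baseline, a test against a 1.5-fold change, the 11 libraries at 24 h against the 6 at 0 h with line ignored, and leaving out each library in turn. After the data were seen, 5 libraries at 24 h were found to stand apart: iFoxA1 replicate 3 and replicate 2 of the 4 other lines. They are called the second library set, and the 12 others the first. Further alternatives were then added: the set as a term (6 residual degrees of freedom), the first set only (2 residual degrees of freedom, from the replicate pairs of iFoxA1 alone), protein-coding genes only, and equal library numbers in iFoxA1. Replicate numbers do not pair the samples, since number 2 belongs to different sets in different groups. The transgene level of 1 line and a few single genes are not reported here. All 17 libraries were kept in every comparison unless a setting says otherwise.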

Results

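Polyadenylated RNA was sequenced from 5 mouse ES cell lines, each with a different Dox-repressible Fox transgene, before Dox removal (0 h, 6 libraries) and after 24 h without Dox in differentiation medium (24 h, 11 libraries). iFoxA1 had 2 libraries at 0 h, with totals of 20.2 and 19.7 M estimated counts, and 3 at 24 h, with 19.3, 17.7 and 37.2 M. The other lines had 1 library at 0 h and 2 at 24 h. Their totals at 0 h were 20.7 M in iFoxC1, 20.5 M in iFoxG1, 18.8 M in iFoxL2 and 22.2 M in iFoxP3. At 24 h, replicates 1 and 2 held 20.3 and 34.1 M in iFoxC1, 18.9 and 33.8 M in iFoxG1, 18.4 and 35.7 M in iFoxL2, and 19.9 and 32.9 M in iFoxP3. The 5 deeper libraries (iFoxA1 replicate 3 and replicate 2 of the other lines) form the second library set. In each of them Mir6236 had the highest TPM of any gene, 31756 to 57882, while mt-Atp8 or Eef1a1 led in the 12 others. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 5213 of 19819 genes between the sets at 24 h, 2524 higher and 2689 lower in the second. None of the second set is at 0 h, so a change from 0 h to 24 h also holds part of the difference between the sets.

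Each line was built to express its own Fox factor once Dox is gone, and the level of this factor is given for 4 lines. Foxa1 in iFoxA1 rose from 1.28 TPM at 0 h (n = 2) to 96.4 ± 64.6 TPM (SD, n = 3), with adjusted p = 0.000623. Foxc1 in iFoxC1 rose from 0.525 to 60.9 ± 18.1 TPM (SD, n = 2), adjusted p = 0.00218. Foxp3 in iFoxP3 rose from 0.533 to 163.9 ± 28.1 TPM (SD, n = 2), adjusted p = 0.000441. Foxl2 in iFoxL2 read 0.485 TPM at 0 h and 78.1 and 2.85 TPM in replicates 1 and 2 at 24 h. Its log2 fold change of 6.14 ± 1.58 (SE) did not pass the threshold (adjusted p = 0.0697). Without replicate 2 it was 7.04, and without replicate 1 it was 3.33. At 24 h each of these 4 factors was higher in its own line than in the 4 other lines, with adjusted p from 1.25e-07 for Foxp3 to 0.00161 for Foxl2. No library of another line exceeded 0.292 TPM for Foxa1, 0.251 for Foxc1, 0.0953 for Foxl2 or 0.430 for Foxp3. In TPM the second library set had less of each of the 4, with a ratio of first to second set of 27.4 for Foxl2, 6.12 for Foxa1, 1.53 for Foxc1 and 1.28 for Foxp3. In CPM, Foxl2 (149.3 and 11.5) and Foxa1 (236.5 and 252.3 in the first set, 76.7 in the second) were lower in the second set, while Foxc1 (274.3 and 288.8) and Foxp3 (218.2 and 246.7) were not. Reads from a transgene and its endogenous gene are counted together, at the mm10 loci of Foxa1 (ENSMUSG00000035451.7, chromosome 12, 57540628 to 57546916), Foxc1 (ENSMUSG00000050295.4, chromosome 13, 31806633 to 31812476), Foxl2 (ENSMUSG00000050397.4, chromosome 9, 98955288 to 98958543) and Foxp3 (ENSMUSG00000039521.13, chromosome X, 7573644 to 7595245).

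**Figure D1:**
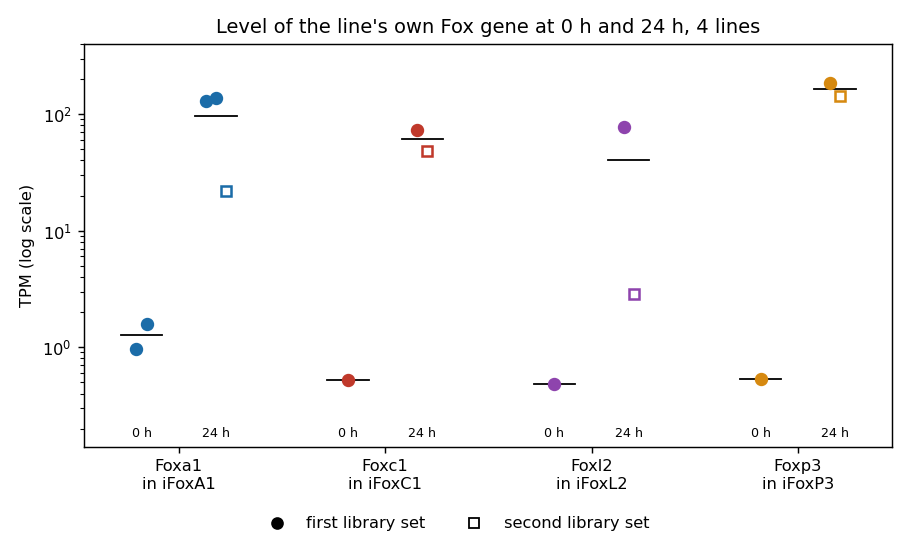
TPM (log scale) of the own Fox gene of 4 lines in every library of the line at 0 h and 24 h; filled circles are the first library set, open squares the second, and black bars the group means. Every 24 h library lies above its line's 0 h libraries, and the lowest, 2.85 TPM of Foxl2, is iFoxL2 replicate 2.

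In the average change over the 5 lines, which includes the loss of Dox and the change of medium, 10 of 17 naive pluripotency genes fell and 17 of 20 formative and primed epiblast genes rose. The naive list lost its camera call when the correlation was estimated (adjusted p = 0.405 with an estimated correlation). In iFoxA1 replicate 3 and iFoxL2 replicate 2 its mean was near that at 0 h (both 6.79 log2 CPM), while its members went both ways from their 0 h levels. Fgf5, a growth factor of the post-implantation epiblast (ENSMUSG00000029337.2, chromosome 5, 98254184 to 98277030), rose from 0.148 ± 0.102 CPM (SD, n = 6) to 15.7 ± 11.7 CPM (SD, n = 11), an average log2 change of 6.73 ± 0.34 (SE). Pou3f1, a POU transcription factor of the primed epiblast, rose from 1.60 ± 0.36 to 61.9 ± 54.7 CPM (4.91 ± 0.09), and Dusp4, a phosphatase of MAP kinases, from 2.84 ± 1.32 to 95.9 ± 31.3 CPM (5.35 ± 0.23). Mras, a small GTPase, fell from 46.1 ± 10.7 to 1.92 ± 0.62 CPM (-4.50 ± 0.21), and Osm, a cytokine of the LIF family, from 6.03 ± 0.80 to 0.263 ± 0.275 CPM (-4.54 ± 0.57). In all, 7501 genes changed on average, 4302 rising and 3199 falling (edgeR, Benjamini-Hochberg).

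Among the 12 genes with the largest average rise were also Hand1 (6.57 ± 0.76), a trophoblast and lateral mesoderm factor; Enpp2 (6.46 ± 0.23), which makes lysophosphatidic acid; Lhx1 (5.99 ± 1.33), a homeobox factor of the anterior mesendoderm; and the clock gene Per2 (4.91 ± 0.25). The others were Car4 (5.76 ± 0.20), Zfp608 (5.26 ± 0.64), Pla2g7 (5.23 ± 0.20), Pde2a (5.09 ± 1.02) and Ccdc194 (5.08 ± 0.34). Fitted folds of Hand1, Lhx1, Car4, Per2 and Ccdc194 are no bounds, because at 0 h they had 0 counts in 1 line, or in 2 lines for Lhx1. Lhx1 and Per2 reached 5 CPM through iFoxA1 alone, with 48.2 and 61.1 CPM at 24 h against at most 1.65 and 2.12 in the other lines, and Pla2g7 read 93.3 CPM there against at most 7.41. The 12 that fell most also held Spic (-3.96 ± 0.30) and Mitf (-3.88 ± 0.19), transcription factors; Inhbb (-4.02 ± 0.38), an inhibin subunit; Cdx1 (-4.33 ± 0.42), a caudal homeobox factor; and Slc51a (-4.67 ± 0.30), a bile acid transporter subunit. Pramel6 (-4.62 ± 0.22), Cybb (-4.24 ± 0.20), Olfr1459 (-4.16 ± 0.14), Hal (-3.84 ± 0.17) and Trpm1 (-3.84 ± 0.30) completed them. Cdx1 exceeded 5 CPM at 0 h in iFoxA1 alone (7.65 against at most 4.33). With the library set as a term 8073 genes passed, 6650 of the 7501 with the same sign, and in the first set alone 12250. All 24 named genes passed in both with the same sign. With each library left out in turn, 23 of them passed in all 17 runs and Lhx1 in 16.

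Of 17 naive pluripotency genes, none rose and 10 fell on average (also 10 adjusted over the list alone; camera adjusted p = 3.53e-06, and adjusted p = 0.405 with an estimated correlation). Nanog, a core factor of the naive state, fell by 2.40 ± 0.39 on the log2 scale, Nr5a2 by 2.12 ± 0.27, Fbxo15 by 1.46 ± 0.12 and the DNA demethylating enzyme Tet2 by 1.10 ± 0.19. Of 20 formative and primed epiblast genes, 17 rose and 2 fell, the same counts adjusted over the list alone (camera adjusted p = 8.19e-09, and adjusted p = 0.0362 with an estimated correlation). Besides Fgf5 and Pou3f1, Sox4 rose by 1.39 ± 0.10 and the DNA methyltransferase Dnmt3a by 1.33 ± 0.10. The mean level of the naive list was 6.87 to 7.18 log2 CPM at 0 h and 4.59 to 5.74 at 24 h, except in iFoxA1 replicate 3 and iFoxL2 replicate 2, which both held 6.79. Relative to 0 h this mean hides members that moved in opposite directions: Nanog fell to 297.3 CPM in iFoxA1 replicate 3, from 589.7 and 579.2 at 0 h, and to 208.6 CPM in iFoxL2 replicate 2, from 611.3. Klf2 rose to 239.8 CPM from 103.7 and 106.2, and to 274.7 CPM from 134.7, in the same libraries. Against the first-set 24 h libraries of the same line, Nanog, Klf2, Klf4, Esrrb, Tfcp2l1 and Zfp42 were all higher in these 2 libraries. Nanog read 51.2 and 50.0 CPM in those of iFoxA1 and 94.2 CPM in that of iFoxL2. The same 2 libraries had the highest mean level of 21 glycolysis and hypoxia genes, 8.72 and 8.77 log2 CPM against at most 8.14 elsewhere. Of the 12 general pluripotency genes, 4 rose and none fell (the same adjusted over the list alone; camera adjusted p = 0.267). Of 14 LIF and STAT3 target genes, 3 rose and 4 fell, the same adjusted over the list alone (camera adjusted p = 0.277). The STAT3 feedback inhibitor Socs3 fell by 2.73 ± 0.14, Bcl3 by 2.78 ± 0.12 and Stat3 itself by 1.47 ± 0.10, while Myc rose by 2.05 ± 0.14. The value of Myc rests on the single iFoxC1 library at 0 h, without which it was 1.15.

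**Figure D2:**
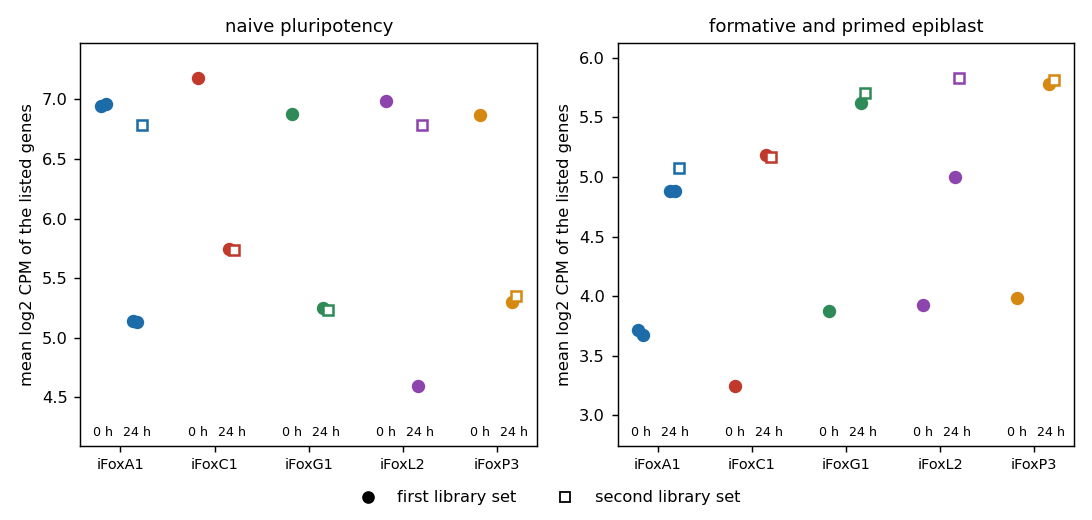
Mean log2 CPM of 17 naive pluripotency genes (left) and 20 formative and primed epiblast genes (right) in each library, by line and time; filled circles are the first library set and open squares the second. The formative list lies at 3.25 to 3.98 at 0 h and 4.88 to 5.83 at 24 h, and the naive list of iFoxA1 replicate 3 and iFoxL2 replicate 2 has a mean of 6.79.

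Epithelial junction genes moved together: 22 of 24 rose and none fell (23 adjusted over the list alone; camera adjusted p = 6.95e-11, and adjusted p = 0.0533 with an estimated correlation). Esrp1, an epithelial splicing regulator, rose by 3.21 ± 0.12, the tight junction gene Cldn3 by 2.01 ± 0.12, Grhl2 by 1.69 ± 0.09 and Epcam by 0.99 ± 0.08. Of 29 forkhead family genes besides the 5 transgenes, 13 rose and 2 fell (15 and 2 adjusted over the list alone; camera adjusted p = 0.00313, and adjusted p = 0.112 with an estimated correlation). Foxp1 rose by 1.66 ± 0.10, Foxj1 by 2.37 ± 0.21 and Foxo4 by 0.77 ± 0.06, while Foxn2 fell by 0.82 ± 0.09. Of 18 trophoblast genes, 11 rose and none fell (12 adjusted over the list alone; camera adjusted p = 0.00402, and adjusted p = 0.353 with an estimated correlation), with Hand1, Krt18 (1.84 ± 0.22) and Ascl2 (2.16 ± 0.32) among them. Of the 13 mitochondrially encoded transcripts, a sign of RNA quality, 8 fell and none rose (10 fell adjusted over the list alone; camera adjusted p = 7.54e-05, and adjusted p = 0.225 with an estimated correlation). Their share of counts was 2.68% to 3.88% at 0 h and 1.85% to 2.88% at 24 h.

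Within single lines, 2133 genes changed in iFoxA1 (1312 rose, 821 fell), 1922 in iFoxC1 (1235, 687), 1115 in iFoxG1 (661, 454), 841 in iFoxL2 (457, 384) and 1198 in iFoxP3 (645, 553), by edgeR with Benjamini-Hochberg adjustment. Fgf5 at 24 h reached 3.23 ± 0.17 CPM in iFoxA1 (SD, n = 3), 8.36 ± 0.73 in iFoxC1, 28.2 ± 1.4 in iFoxG1, 16.1 ± 10.0 in iFoxL2 and 29.0 ± 3.6 in iFoxP3 (SD, n = 2 each). Pou3f1 reached 9.95 ± 0.93, 31.1 ± 0.2, 158.7 ± 7.2, 52.3 ± 2.1 and 83.2 ± 6.6 CPM in the same order. The formative list passed camera within each line, and with an estimated correlation its adjusted p was 0.0407 in iFoxA1, 0.0188 in iFoxC1, 0.0272 in iFoxG1, 0.0643 in iFoxL2 and 0.0212 in iFoxP3. Genes called the same way in all 5 lines numbered 207. Between iFoxG1 and iFoxP3, 404 genes rose in both lines and 296 fell in both, where 21.5 and 12.7 would be shared by independent lists, and 3 went opposite ways. Between iFoxA1 and iFoxC1, 382 rose and 227 fell in both, and 52 went opposite ways. Across the 19819 genes, which are not independent replicates, the changes of 2 lines correlated with Pearson r from 0.385 (iFoxC1 and iFoxL2) to 0.579 (iFoxG1 and iFoxP3, Spearman rho 0.719), and from 0.303 to 0.438 in the first library set. In that set, over named protein-coding genes with a mean of at least 5 CPM at the higher time, r was higher, 0.547 to 0.854. With the library set as a term the counts were 3643, 3723, 2398, 1904 and 2799 in that order of lines, and they held 2131, 1922, 1112, 841 and 1198 of the calls above with the same sign. In the first set alone, where the spread comes from the replicate pairs of iFoxA1, they were 9100, 8866, 7911, 8246 and 8438. The counts within lines depended on single libraries: iFoxA1 ranged from 551 without its 0 h replicate 1 to 3237 without iFoxL2 24 h replicate 2, iFoxC1 from 417 without its own 24 h replicate 2 to 3243, and iFoxG1 from 275 without its own 24 h replicate 2 to 2135. iFoxL2 ranged from 326 without iFoxA1 0 h replicate 2 to 1750, iFoxP3 from 271 without its own 24 h replicate 1 to 2396, and the shared 207 from 75 without iFoxA1 0 h replicate 2 to 414; the highest values came without an iFoxL2 24 h library.

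In iFoxA1, 613 genes changed differently from the mean of the 4 other lines (the line-specific change), 276 upward and 337 downward (edgeR, Benjamini-Hochberg). Calca, which encodes calcitonin and CGRP, rose from 6.52 ± 0.84 CPM (SD, n = 2) to 177.9 ± 96.8 CPM (SD, n = 3), a line-specific log2 change of 5.20 ± 0.78 (SE). Emp2, an epithelial membrane protein, rose from 7.36 ± 0.13 to 144.5 ± 45.5 CPM (5.09 ± 0.56). Zbtb16, a zinc finger factor (6.31 ± 1.22), the protease Tll1 (4.92 ± 0.65), Timp4, an inhibitor of metalloproteinases (4.74 ± 0.81), the G protein subunit Gna14 (4.49 ± 0.55), Creg2 (4.53 ± 0.67) and Pkd1l1 (6.60 ± 1.09) rose as well. Pkd1l1 had 1 count at 0 h and was 454 times higher at 24 h (95% counting interval 81.2 to 17950). Relative to the other lines, Fgf17 (-3.12 ± 0.60), the Hedgehog effector Gli1 (-2.28 ± 0.49), Tgfbi (-2.67 ± 0.43), Parp14 (-2.20 ± 0.37), Soga3 (-3.06 ± 0.60), Map1a (-2.56 ± 0.48), Crocc2 (-2.29 ± 0.19) and Calml4 (-2.24 ± 0.38) fell. All 16 also differed from the other lines at 24 h in the same direction, as did 492 of the 613, while 156 of the 613 differed more from the other lines at 0 h than at 24 h. Of the 16, only Crocc2 passed the line-specific test in all 13 runs that left out a library, while Fgf17, Gli1 and Soga3 passed in 3, Map1a in 5 and Zbtb16 in 6. The count was 50 without iFoxA1 0 h replicate 2 and 1540 without iFoxL2 24 h replicate 2. With iFoxA1 held to 3 libraries, like every other line, edgeR called 3 genes (10 with the library set as a term). With all libraries, the set as a term gave 1545 genes, 612 of the 613 among them, and the first set alone 7191.

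Several gut epithelium and endoderm genes rose within iFoxA1. These changes include any change shared by the lines, and in the average over the 5 lines Krt18, Cldn3 and most epithelial junction genes also rose. Shh and Lhx1 were higher in iFoxA1 than in the other lines at 24 h. Of 13 hepatocyte and gut epithelium genes, 5 rose within the line and none fell (9 and 1 adjusted over the list alone; camera adjusted p = 7.89e-05, and adjusted p = 0.0407 with an estimated correlation), among them the keratin Krt7 (4.06 ± 0.63), the brush border gene Vil1 (2.08 ± 0.35), Krt18 (2.78 ± 0.38) and Cldn3 (2.32 ± 0.21). Of 17 definitive and foregut endoderm genes, 4 rose and none fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.0239, and adjusted p = 0.227 with an estimated correlation). Of these, Lhx1 went from 0 counts to 48.2 ± 37.5 CPM, at least 549-fold higher. Shh, the Hedgehog ligand of foregut endoderm and notochord, went from 1 count to 41.9 ± 29.7 CPM, a ratio of 1457 (95% counting interval 261 to 57580). Prox1 rose by 2.94 ± 0.70 and Cldn6 by 1.75 ± 0.43. Epithelial junction genes rose in iFoxA1 too, 12 of 24 with none falling (18 adjusted over the list alone; camera adjusted p = 2.71e-09, and adjusted p = 0.0443 with an estimated correlation). Set against the other lines, the change of 1 of 20 formative genes was higher in iFoxA1 and that of 6 lower (3 and 8 adjusted over the list alone; camera adjusted p = 0.00717, and adjusted p = 0.118 with an estimated correlation). Pou3f1 rose by 2.56 ± 0.13 within iFoxA1, with a line-specific change of -2.94 ± 0.15, and the line-specific change was -1.49 ± 0.22 for Dnmt3b, -2.51 ± 0.40 for Sall2 and 2.88 ± 0.57 for the Nodal antagonist Lefty1. Of 17 Wnt targets 3 had a lower change than in the other lines (also 3 adjusted over the list alone; camera adjusted p = 0.0123, and adjusted p = 0.118 with an estimated correlation), Ccnd1 (-1.26 ± 0.16), Nkd1 (-1.92 ± 0.41) and Axin2 (-1.90 ± 0.42). With a library left out, Lefty1, Nkd1 and Axin2 passed in 3 of 13 runs in the line-specific test, and Cldn6 in 5 within the line.

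Before Dox removal iFoxA1 already differed from the other lines in primitive and visceral endoderm genes, an observation made after the values were seen on a list fixed earlier. Foxa1 itself was not absent: it read 1.87 and 3.05 CPM in the iFoxA1 0 h libraries, against at most 0.284 CPM in the other lines. This was not particular to iFoxA1. At 0 h Foxc1 read 1.94 CPM in iFoxC1 against at most 0.162 in the other lines. Foxl2 read 1.14 in iFoxL2 against at most 0.144, and Foxp3 0.645 in iFoxP3 against at most 0.206. Whether the Foxa1 level and the endoderm genes of iFoxA1 are related was not tested. In both iFoxA1 0 h libraries 19 of the 24 genes were higher than in all 4 other lines (a given line of 5 is highest by chance for 20% of genes, as the 2 libraries of a line are not independent), and 8 differed among the lines at 0 h by edgeR with Benjamini-Hochberg adjustment. The 19 include genes near the floor, such as Ttr (at least 0.0479 CPM against at most 0.0474). The basement membrane collagens Col4a2 and Col4a1 read 122.4 and 226.4 CPM against means of 8.65 and 20.6 in the other lines (adjusted p = 9.49e-05 and 0.00369). The endoderm factors Gata6 (12.6 against 0.763 CPM, adjusted p = 0.00369), Gata4 (13.0 against 0.722, adjusted p = 0.0284) and Sox17 (6.04 against 0.179, adjusted p = 0.0306), the receptors Cubn (56.6 against 0.549, adjusted p = 0.00909) and Pdgfra (24.2 against 0.989, adjusted p = 0.0306) and the laminin Lama1 (208.3 against 39.4, adjusted p = 0.0220) were the others. The median difference of the 24 genes was 1.84 on the log2 scale, against 0.02 for all genes. Of the 8 calls, 2 were left without iFoxA1 0 h replicate 1 and 3 without replicate 2, where the whole count at 0 h was 2 and 6, and 4 to 8 were left without any other library tested. Over the following 24 h in iFoxA1, 5 of the 24 rose and 2 fell.

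**Figure D3:**
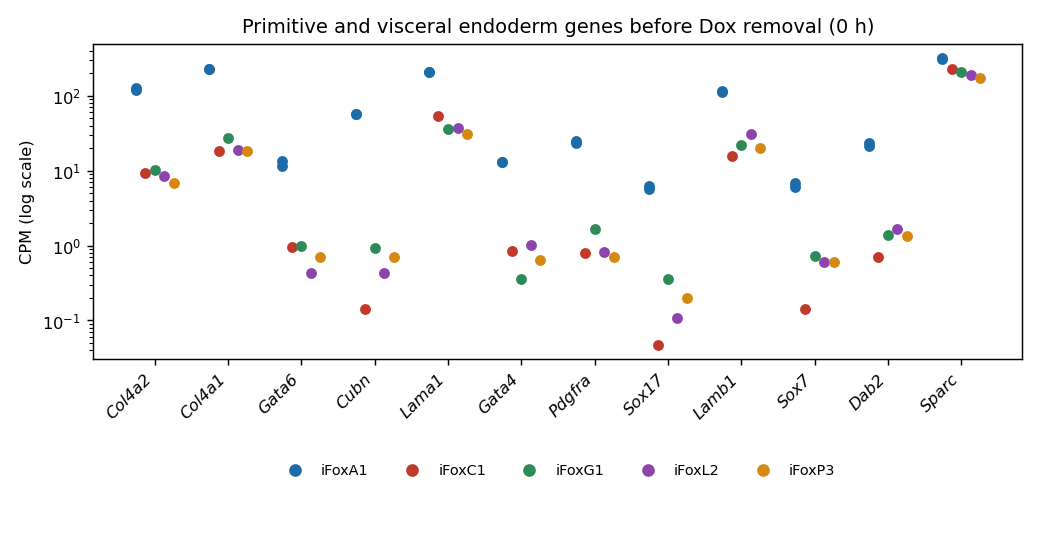
CPM (log scale) of the 12 primitive and visceral endoderm genes with the smallest p among lines at 0 h, in each 0 h library, coloured by line (2 points for iFoxA1, 1 for each other line). Both iFoxA1 points lie above all other lines for all 12 genes, from Col4a2 (122.4 against 8.65 CPM on average) to Sparc (312.7 against 199.6 CPM).

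iFoxC1 had 212 line-specific changes, 132 up and 80 down (edgeR, Benjamini-Hochberg). Cholesterol synthesis genes fell in this line: within it 10 of 21 fell and none rose (14 adjusted over the list alone; camera adjusted p = 9.93e-10, and adjusted p = 0.0188 with an estimated correlation). Relative to the other lines 6 fell and none rose (13 adjusted over the list alone; camera adjusted p = 1.50e-12, and adjusted p = 0.0170 with an estimated correlation). Insig1, a regulator of sterol sensing, fell by 1.83 ± 0.24 relative to the other lines, Stard4 by 1.49 ± 0.25 and Dhcr7 by 1.54 ± 0.28, calls that passed in 10, 5 and 3 of the 13 runs that left out a library. None of these runs could leave out the single iFoxC1 0 h library, on which these changes also rest. Insig1 differed from the other lines by 1.05 log2 CPM at 0 h and by -0.769 at 24 h. The mean level of the list in iFoxC1 was 6.53 log2 CPM at 0 h, where the other lines lay between 6.04 and 6.20, and 5.71 and 5.62 at 24 h, where they lay between 5.73 and 6.30. Glycolysis and hypoxia genes also had a lower line-specific change in iFoxC1 by camera (adjusted p = 0.000187, and adjusted p = 0.749 with an estimated correlation), with 0 of 21 genes past the threshold in edgeR, over all genes or adjusted over the list alone. The single iFoxC1 0 h library had the highest mean of this list at 0 h, 8.14 log2 CPM against at most 7.39, and iFoxA1 replicate 3 and iFoxL2 replicate 2 (8.72 and 8.77) are among the libraries it is compared with.

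**Figure D4:**
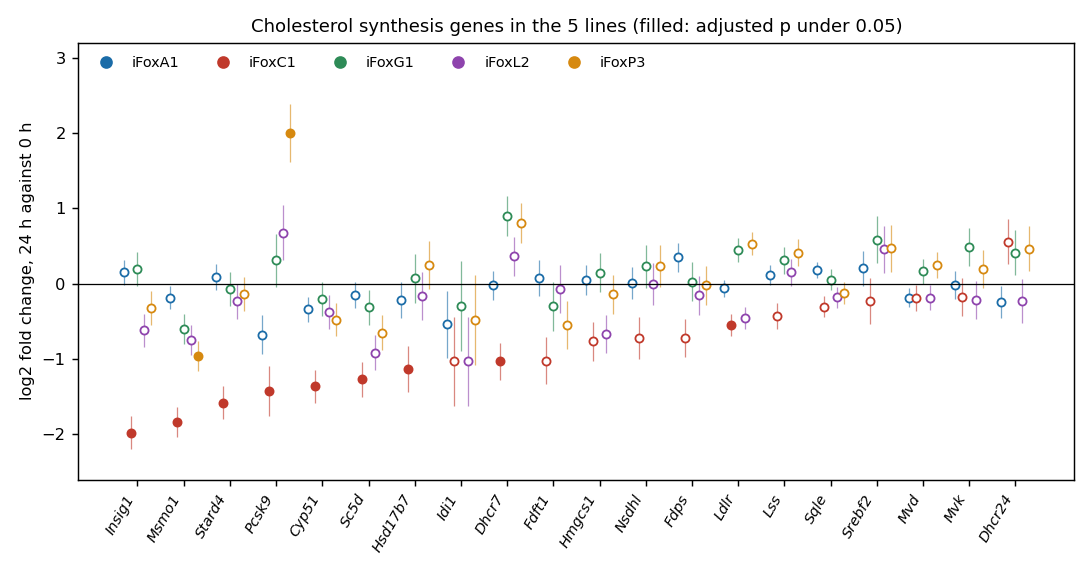
Log2 fold change from 0 h to 24 h (± SE) of 20 of the 21 cholesterol synthesis genes within each of the 5 lines, coloured by line; filled points passed adjusted p 0.05 and open points did not. In iFoxC1, 9 of the genes shown fell, with Insig1 at -1.98 and Msmo1 at -1.83.

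Myc, a growth-promoting transcription factor, rose more in iFoxC1 than elsewhere (line-specific log2 change 4.51 ± 0.40), as did Ptgs1, a cyclooxygenase (4.33 ± 0.79), the transglutaminase Tgm3 (4.32 ± 0.46), Enpp2 (4.35 ± 0.70), Enox1 (4.07 ± 0.41), the parathyroid hormone receptor Pth1r (3.72 ± 0.48), Ccdc194 (7.02) and Car4 (6.36). S100a1 (-4.02 ± 0.60) and S100a13 (-2.24 ± 0.43), calcium-binding proteins, the receptor kinase Grk3 (-2.79 ± 0.53), Lama1 (-2.36 ± 0.38), Ank3 (-2.29 ± 0.27), Ppp6r2 (-2.02 ± 0.28), Usp29 (-1.88 ± 0.32) and Insig1 fell relative to the other lines. Car4 and Ccdc194 had 0 counts at 0 h in iFoxC1 and were at least 67.1-fold and 60.1-fold higher at 24 h, so their fitted values are no bounds. At 24 h Car4 was lower in iFoxC1 than in the other lines (-1.36 ± 0.20). The single 0 h library of iFoxC1 carries much of this: 151 of the 212 genes differed more from the other lines at 0 h than at 24 h, and 86 also differed at 24 h in the same direction. Myc read 1.66 CPM there against 25.1 to 30.1 CPM in the other lines at 0 h, and Enox1 5.02 against 56.2 to 77.1 CPM. Of the 16 named genes, 9 differed at 24 h in the same direction, namely Ptgs1, Tgm3, Enpp2, Pth1r, Grk3, Lama1, Ank3, Ppp6r2 and Insig1. In the line-specific test Myc, Tgm3 and Enox1 passed in all 13 runs that left out a library, while Ptgs1, Ccdc194, S100a13, Grk3 and Usp29 passed in 3 and Enpp2 and Lama1 in 4. None of these runs could leave out the single iFoxC1 0 h library, so they do not test the calls that rest on it. Against the other lines at 24 h, Myc and Enox1 did not pass (edgeR, adjusted p = 0.2769 and 0.5515). The count was 8 without iFoxC1 24 h replicate 1, 1069 without iFoxL2 24 h replicate 1, 1183 with the library set as a term (all 212 among them) and 6506 in the first set alone.

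iFoxG1 had 22 line-specific changes, 11 up and 11 down (edgeR, Benjamini-Hochberg). Cdkn1c, which encodes the cyclin-dependent kinase inhibitor p57, rose from 5.70 to 118.7 ± 16.9 CPM (SD, n = 2), a line-specific log2 change of 3.04 ± 0.35 (SE). Pdzk1, a scaffold protein of epithelial transporters, rose from 1.23 to 39.7 ± 2.7 CPM (3.91 ± 0.54) and the stress-response gene Gadd45g from 2.52 to 58.4 ± 2.4 CPM (3.26 ± 0.28). Sall3, a zinc finger factor, rose to 17.9 ± 2.5 CPM from 7.97 while it read 1.69 to 3.50 CPM on average in the other lines at 24 h (2.92 ± 0.29). Trib2 (2.75 ± 0.40), Ier5 (2.66 ± 0.36), Serinc5 (2.28 ± 0.25) and Pou3f1 (1.93 ± 0.19) rose, and Cgnl1, a cell junction gene (-2.40 ± 0.31), the macroH2A gene H2afy2 (-1.46 ± 0.18), the thrombin receptor F2r (-1.39 ± 0.20) and the cell cycle kinase Cdk6 (-1.37 ± 0.20) fell relative to the other lines. All 22 differed from the other lines at 24 h in the same direction. None of the 12 named genes passed the line-specific test in all 13 runs that left out a library: Gadd45g passed in 12, Cdkn1c in 7, Ier5 in 4, and Pdzk1, Trib2, Cgnl1, H2afy2, F2r and Cdk6 in 3. The count was 1 without iFoxG1 24 h replicate 1, 90 without iFoxL2 24 h replicate 1, 57 with the library set as a term (21 of the 22 among them) and 2496 in the first set alone.

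iFoxL2 and iFoxP3 had the fewest line-specific calls. Few calls do not show a small response, since the edgeR line-specific test also missed the own Fox genes of these lines. The line-specific log2 change of Foxp3 in iFoxP3 was 8.24 (adjusted p = 0.267). That of Foxl2 in iFoxL2 was 3.91 and did not pass either. The only line-specific call of iFoxL2, Gm13502, a processed pseudogene named here after its value was seen, had 0 counts at 0 h in that line and 4.93 to 8.97 CPM in the others. DESeq2 called 62 genes in iFoxL2, the library set as a term 10, the first set alone 2891 and the fit without iFoxL2 24 h replicate 1 called 102. In iFoxP3, edgeR called 0 genes (785 at an unadjusted p under 0.05), DESeq2 called 25, and limma called 5 on log2(TPM + 1) and 2 on log2(TPM + 0.1), and the first set alone gave 3429. A test of any difference among the 5 changes called 195 genes, 953 with the library set as a term and 9717 in the first set alone. Without iFoxA1 0 h replicate 2 it called 13, and without iFoxL2 24 h replicate 1 it called 1046.

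The lines were also compared with each other at 24 h, where all groups had replicates but differences present at 0 h are included. The genes named here were picked after their values were seen. In iFoxA1, 2998 genes differed from the mean of the other lines, 1760 higher and 1238 lower (edgeR, Benjamini-Hochberg). Shh read 41.9 CPM against 0.218 on average in the other lines, the muscle RNA-binding protein Rbm24 7.30 against 0.160 and the substance P receptor Tacr1 7.01 against 0.0879. Their fitted folds are no bounds and are not given, since some libraries of other lines had 0 counts. Irgm1, an interferon-induced GTPase, was lower (-2.55 ± 0.20 on the log2 scale). In iFoxC1, 731 genes differed (478 higher, 253 lower). Hand1 read 38.3 ± 4.9 CPM (SD, n = 2) against 5.28 elsewhere (3.04 ± 0.55). Pdx1, a pancreas and duodenum factor, had 0 counts at 0 h and 5.46 ± 0.71 CPM at 24 h, at least 39.3-fold higher, and stood 4.80 ± 0.61 above the other lines. The retinoic acid hydroxylase Cyp26a1 was higher by 2.37 ± 0.32 and Lama1 lower (-2.37 ± 0.27). In iFoxG1, 543 genes differed (298 higher, 245 lower). Sox1, a neural plate factor, read 16.7 CPM against 2.27 (2.89 ± 0.27), and the Nodal antagonist Lefty2 read 3.37 CPM against 50.8 (-3.74 ± 0.79, adjusted p = 0.0398), a call that passed in 3 of the 13 runs that left out a library. Of the genes named for iFoxC1, Hand1 passed in 9 of these, Cyp26a1 in 11, and Pdx1 and Lama1 in 12.

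In iFoxL2, 324 genes differed (221 higher, 103 lower). Gchfr, a regulator of tetrahydrobiopterin synthesis, read 25.3 CPM against 2.87 (3.13 ± 0.43), the kinesin Kif1a was higher by 2.19 ± 0.31, and the tubulin Tubb2a was lower, 29.6 against 82.2 CPM (-1.41 ± 0.11). These calls rest on libraries that differ: replicate 2 had 2.85 TPM of Foxl2 against 78.1 in replicate 1. Without replicate 2, 152 of the 324 passed with the same sign, and without replicate 1, 264. The difference of iFoxL2 from the other lines correlated between the library sets with Pearson r = 0.139 across genes. For Kif1a it was 2.94 in the first set and 1.05 in the second, and for Tubb2a -1.21 and -1.61. Gchfr differed more in the second set (3.54) than in the first (2.08). It read 10.88 CPM in replicate 1 and 39.75 CPM in replicate 2, the library with less Foxl2. In iFoxP3, 110 genes differed (58 higher, 52 lower). The piRNA pathway gene Tdrd5 was higher by 2.26 ± 0.25, Irgm1 by 2.23 ± 0.17 and the synaptotagmin Syt13 by 1.98 ± 0.23, and Cd63 was lower, 64.5 against 140.0 CPM (-0.99 ± 0.13). Of the 13 runs that left out a library, Tubb2a passed in 13, Gchfr and Irgm1 in 12, and Kif1a, Tdrd5, Syt13 and Cd63 in 11. The lowest counts without a library were 1598 for iFoxA1 (without its 24 h replicate 1), 98 for iFoxC1, 68 for iFoxG1 and 1 for iFoxP3 (each without its own 24 h replicate 2), and 71 for iFoxL2 (without iFoxG1 24 h replicate 1). The highest were 4190 for iFoxA1 without iFoxL2 24 h replicate 2, and 1734 for iFoxC1, 1086 for iFoxG1, 1915 for iFoxL2 and 457 for iFoxP3 without iFoxL2 24 h replicate 1. With the library set as a term the counts were 4666, 1660, 1151, 1274 and 353 from iFoxA1 to iFoxP3, and in the first set alone 9688, 5157, 4474, 5854 and 3238.

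**Figure D5:**
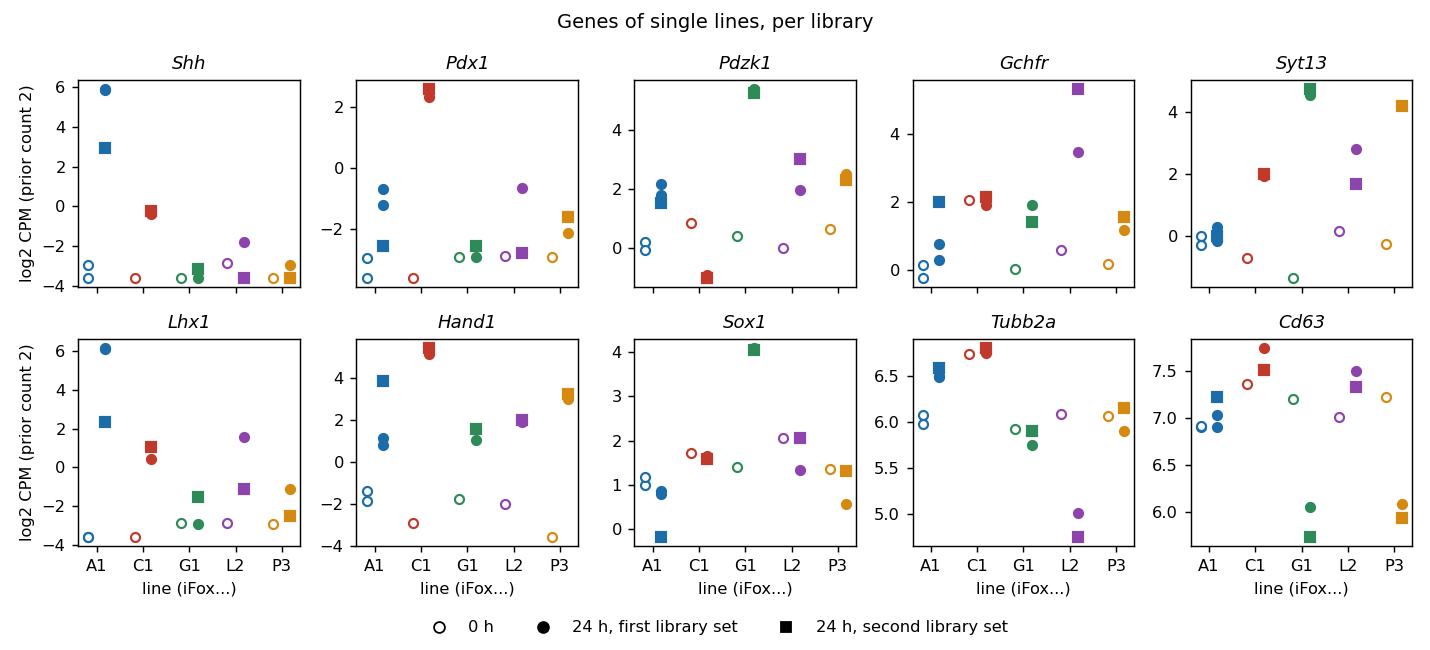
Log2 CPM (prior count 2) of 10 genes of single lines in every library, by line; open circles are 0 h, filled circles 24 h of the first library set and filled squares 24 h of the second. Shh and Lhx1 stand out in iFoxA1, Pdx1 and Hand1 in iFoxC1, Pdzk1 and Sox1 in iFoxG1, Gchfr (higher) and Tubb2a (lower) in iFoxL2, and Syt13 (higher) and Cd63 (lower) in both iFoxP3 and iFoxG1, with Pdzk1 at 39.7 CPM in iFoxG1 against 3.74 elsewhere.

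Among the lines at 0 h, 98 genes differed (edgeR F test, Benjamini-Hochberg). The line farthest from the mean of the others was iFoxC1 for 59 of them (22 higher, 37 lower), iFoxA1 for 35 (33 higher, 2 lower), iFoxP3 for 3 and iFoxL2 for 1. Besides the endoderm genes, iFoxA1 had more of the proteoglycan gene Srgn (14.8 against at most 1.33 CPM), of the forkhead gene Foxq1 (9.43 against at most 0.298) and of cyclin D1, Ccnd1 (129.5 against 39.4 to 72.9). iFoxC1 had more Necap1 (206.2 against 63.5 to 77.5 CPM), Scml2 (25.3 against at most 5.66) and Bcl2l14 (30.4 against at most 5.61), and less Esrp1 (1.33 against 7.96 to 16.1), Spry2 (23.4 against 61.3 to 80.9) and Jade2 (6.30 against 17.9 to 45.4). These genes were also named after their values were seen. The count was 2 without iFoxA1 0 h replicate 1 and 491 without iFoxL2 24 h replicate 2, 697 with the library set as a term and 10469 in the first set alone.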

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

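Of the tests reported here, those of shared reads, of the formative list in 2 libraries and of the transgene level across lines were chosen only after the results they measure were seen.

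The change from 0 h to 24 h differed between the lines by tests of the difference itself in edgeR with Benjamini-Hochberg adjustment. Any difference among the 5 lines was called for 195 genes. The line-specific change was called for 613 genes in iFoxA1, 212 in iFoxC1, 22 in iFoxG1 and 1 in iFoxL2. Calca and Emp2 in iFoxA1, Ptgs1 and Insig1 in iFoxC1, and Cdkn1c and Pdzk1 in iFoxG1 are among the genes behind these counts. Of 30 splits of the 17 libraries into 11 and 6, the real one of 24 h against 0 h gave 6319 genes and was the only one (1 of 30) to give as many. The highest other gave 366, so a random grouping by time is argued against. For the 3 iFoxA1 libraries against the 8 others at 24 h, the real split of 30 gave 1595 genes and the highest other 2 (1 of 30 as large). With the library set as a term these were 1976 and 2 (1 of 30 as large). That cannot exclude chance for a line, since the other splits mix lines and the libraries of a line are not independent. Neither set of splits tests the difference between the changes.

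The first pattern is the second library set: iFoxA1 replicate 3 and replicate 2 of the other lines at 24 h, which differ from the 6 first-set libraries at 24 h in 5213 genes, and from all 12 others in Mir6236. Greater depth is argued against, since 4942 genes were called after the 5 libraries were thinned to the mean total of the others. Reads shared between near-identical copies and pseudogenes are argued against as the whole cause, since 29.16% of protein-coding genes with a mean of 5 CPM or more were called (2898 of 9937). Separate library preparation, sequencing or culture may lie behind it and stays open, since the labels name no batch; no biological explanation was tested, because the set holds every line.

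The second pattern is within that set: iFoxL2 replicate 2 and iFoxA1 replicate 3 had less of their transgene than the first set (11.5 against 149.3 CPM of Foxl2, and 76.7 against 236.5 and 252.3 CPM of Foxa1), and a mean of naive pluripotency genes near that at 0 h, though Nanog lay below its 0 h level in both (297.3 and 208.6 CPM) and Klf2 above (239.8 and 274.7 CPM). Libraries of uninduced cells at 0 h under a 24 h label are argued against, since Fgf5 and Pou3f1 were at least 5.745 times the highest 0 h library in both. Both genes rose in every line, so they cannot show whether cells moved to differentiation medium were well induced. Poor induction of such cells stays open. A smaller response to the change of medium is argued against for the mean of the formative list only. In both libraries it lay at least 0.1918 log2 CPM above the first-set libraries of its line, where the sets differed by at most 0.0858 in the 3 other lines. Members went both ways. Otx2 was above the first set in both (163.3 and 372.1 CPM), while Fgf5 in iFoxA1 replicate 3 (3.04 CPM) and Dnmt3b in iFoxL2 replicate 2 (381.2 CPM) lay below it. Nanog and Klf2 were above the first set in both, so a smaller response of naive genes stays open. A culture difference with higher glycolysis and hypoxia genes stays open and may have acted with the lower transgene level: their mean log2 CPM was at least 0.5761 above all 15 other libraries, with Slc2a1 at 1092 and 1589 CPM and Bnip3 at 632 and 496 CPM in iFoxA1 replicate 3 and iFoxL2 replicate 2. No other biological explanation was tested, since both libraries are replicates of groups whose other libraries differ.

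The third pattern is that iFoxA1 had the most line-specific calls. That iFoxA1 had more libraries (5 against 3) cannot be told apart from an effect of the factor. With 3 libraries iFoxA1 still had the most calls, 3 against 1 in the next line (10 against 1 with the library set as a term). This was the outcome predicted if library number was not the cause. However, 3 against 1 is too small a difference to decide it. The gap of 10 against 1 does not decide it either, since genes of the same libraries are not independent. Holding iFoxA1 to 3 libraries also loses the only replicate pairs within a library set. The iFoxA1 transgene was highest neither in TPM, where the first set had 0.727 times the level of iFoxP3, nor in CPM, where it had 0.891 times that of iFoxC1, but both units depend on lengths that differ between the genes. Per kb of coding sequence, the part a transgene holds, its first set was 1.027 times iFoxP3 with overlapping libraries (168.4 and 179.7 against 169.5 and 191.7 CPM per kb). iFoxA1 replicate 3, which is also in the fit, had 54.65 CPM per kb. No clearly higher transgene level was thus seen in iFoxA1 than in iFoxP3, which had 0 line-specific calls. The question cannot be decided further, for want of libraries at levels this close. The identity of the factor, and differences between the lines present at 0 h, remain open and untested.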

How the results depend on the processing

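The library set as a term, the first set only, protein-coding genes only and equal library numbers were chosen after the data were seen; the other alternatives were chosen before. Counts given as 5 values run from iFoxA1 to iFoxP3, and the cause of a change was not tested unless one is named. With RLE size factors all 24 results of the comparisons stayed the same. Counts were within 1.5 times, and the transgene changes kept their direction and side of the threshold. Of these results only the transgene changes could reverse, since a count of calls has no direction, and none of them did under any setting run. Of the 127 single genes that the naming rules pick for the average, line-specific and 24 h comparisons, 126 stayed past the threshold with RLE size factors, 124 with DESeq2, 117 without the low-count filter, 70 on log2(TPM + 1) and 63 on log2(TPM + 0.1). The only one that reversed was Car4 in the line-specific change of iFoxC1, at -0.29 by limma on log2(TPM + 1); it had 0 counts at 0 h, and the cause was not tested.

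With DESeq2 the counts within lines were 2913, 3072, 2056, 1858 and 2396, the line-specific counts 1441, 1015, 148, 62 and 25, and the counts at 24 h 3603, 1361, 1025, 1149 and 465. It gave 7942 genes on average, 1632 for any difference among the changes, 1247 at 0 h and 429 in all 5 lines. It kept 2052 of the 2133 calls within iFoxA1, 1842 of the 1922 in iFoxC1, 1062 of the 1115 in iFoxG1 and 796 of the 841 in iFoxL2 with the same sign. Without the low-count filter, which tests more genes, the counts within lines were 1549, 1099, 673, 456 and 568, the line-specific counts 306, 77, 15, 1 and 1, and 118 genes were called in all 5 lines.

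With the replicate block, the counts within lines were 2879, 3209, 1956, 1603 and 2294, and at 24 h 4655, 1471, 1003, 1609 and 325. The line-specific counts in iFoxA1, iFoxC1 and iFoxG1 were 1054, 754 and 69, and the block gave 617 for any difference, 315 at 0 h and 366 in all 5 lines. Replicate numbers pair no samples, but among the lines other than iFoxA1 they coincide with the library set at 24 h, so the block takes up part of that difference.

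By limma on log2(TPM + 1) the counts within lines were 1162, 658, 439, 272 and 422, the line-specific counts 204, 42, 7, 4 and 5, and the counts at 24 h 1298, 207, 203, 8 and 13. There were 4473 genes on average, 48 for any difference, 53 at 0 h and 77 in all 5 lines. On log2(TPM + 0.1) they were 1072, 492, 425, 228 and 449 within lines, 146, 13, 3, 3 and 2 line-specific, and 1328, 155, 138, 3 and 5 at 24 h, with 4600, 27, 21 and 58 for the other 4 results in that order. The cause was not tested.

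Fitting only a line's own libraries left 1 or 3 residual degrees of freedom and gave 1749, 410, 292, 0 and 0 genes within lines, and so 0 in all 5. In that edgeR fit, 683 genes in iFoxL2 and 4176 in iFoxP3 had an unadjusted p under 0.05, where DESeq2 on all libraries called 1858 and 2396, limma 272 and 422 on log2(TPM + 1), and 228 and 449 on log2(TPM + 0.1). A common 0 h baseline, which adds the differences between lines at 0 h to the change, gave 5744, 4002, 3954, 4891 and 3425, with 1245 in all 5 lines. Testing against a 1.5-fold change, a stricter question by construction, gave 886, 648, 413, 228 and 258 within lines, 2084 on average and 57 in all 5 lines. The line-specific counts under it were 136 in iFoxA1, 28 in iFoxC1 and 10 in iFoxG1. The 11 libraries at 24 h against the 6 at 0 h with line ignored gave 6319 genes.

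With the library set as a term the counts within lines were 3643, 3723, 2398, 1904 and 2799, and at 24 h 4666, 1660, 1151, 1274 and 353. The line-specific counts were 1545, 1183, 57 and 10 from iFoxA1 to iFoxL2, with 953 for any difference, 697 at 0 h and 456 in all 5 lines. In the first set alone they were 9100, 8866, 7911, 8246 and 8438 within lines, 7191, 6506, 2496, 2891 and 3429 line-specific, and 9688, 5157, 4474, 5854 and 3238 at 24 h, with 12250 on average, 9717 for any difference, 10469 at 0 h and 2247 in all 5 lines. By construction the first set takes its spread from the close pairs of iFoxA1 alone, so these counts hold only if single libraries of the other lines vary as little. Protein-coding genes only gave 349 for any difference, 154 at 0 h, 561 in iFoxL2 and 166 in iFoxP3 at 24 h, and 0 line-specific calls in iFoxL2 by edgeR, where the only call had been a pseudogene (937 at an unadjusted p under 0.05; all genes: 62 by DESeq2, 4 and 3 by limma). With equal library numbers iFoxA1 had 165 genes within the line, 3 line-specific and 1047 at 24 h; the fit then has fewer libraries and no replicate pair within a set.

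Foxl2 in iFoxL2 (6.14, adjusted p = 0.0697) passed the threshold with DESeq2 (6.16, adjusted p = 0.000134), without the low-count filter (6.14, adjusted p = 0.0237), with the replicate block (6.50, adjusted p = 0.0277), with a common 0 h baseline (11.5, adjusted p = 0.000258), with the library set as a term (6.54, adjusted p = 0.0120), in the first set alone (7.04, adjusted p = 1.51e-07) and with protein-coding genes only (6.13, adjusted p = 0.0469). Foxp3 in iFoxP3 missed it in the fit of that line's own 3 libraries (8.49, adjusted p = 0.0860), which has fewer samples. Of list and contrast pairs, 64 passed camera, 9 with the correlation estimated (7 up, 2 down), 97 by fry, 73 with the library set as a term and 90 in the first set alone. The median Pearson r of the changes of 2 lines was 0.481, and 0.298 with the genes of the average change left out, 0.621 on log2(TPM + 1), 0.439 with the library set as a term and 0.338 in the first set alone.

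Leaving out each library in turn, the counts ranged from 6093 to 8452 for the average change, 551 to 3237 within iFoxA1, 417 to 3243 in iFoxC1, 275 to 2135 in iFoxG1, 326 to 1750 in iFoxL2 and 271 to 2396 in iFoxP3. Any difference among the changes ranged from 13 to 1046, the line-specific counts from 50 to 1540 in iFoxA1, 8 to 1069 in iFoxC1, 1 to 90 in iFoxG1, 1 to 102 in iFoxL2 and 0 to 2 in iFoxP3 (where edgeR gave 0, 576 to 1212 genes had an unadjusted p under 0.05, beside 25 genes called by DESeq2, 5 and 2 by limma on all libraries). At 24 h the ranges were 1598 to 4190, 98 to 1734, 68 to 1086, 71 to 1915 and 1 to 457, at 0 h 2 to 491, and in all 5 lines 75 to 414. Most lowest values came without an iFoxA1 0 h library or one of the line's own 24 h libraries, as the report names them, and all highest ones for counts without iFoxL2 24 h replicate 1 or 2. The induced transgenes ranged from 5.95 to 6.65 for Foxa1, 7.09 to 7.21 for Foxc1 and 8.38 to 8.57 for Foxp3. Foxl2 ranged from 3.33 without replicate 1 to 7.04 without replicate 2, where it passed (adjusted p = 0.00239). Of the 127 single genes, 86 to 127 stayed past the threshold in a run, and none reversed. All runs were passed by 23 of the 24 genes of the average change and by 1 of 16, 3 of 16 and 0 of 12 in the line-specific changes of iFoxA1, iFoxC1 and iFoxG1. For the comparisons at 24 h these were 12 of 12, 3 of 12, 8 of 12, 5 of 12 and 0 of 11. A line's only 0 h library could be left out for the average change alone, since its own change then has no baseline. With 17.7 to 37.2 M counts per library, depth limits the genes near the floor of 3 counts, whose folds are given as bounds or with counting intervals.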

Other observations

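The comparison of the lines between the library sets was chosen after the sets were seen. The lists below were fixed before the data were examined, and their counts are from edgeR with Benjamini-Hochberg adjustment.

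Beyond the lists in the report, no other list passed camera for the average change, although single members changed. Of 18 primitive streak and mesoderm genes, 6 rose and 3 fell, the same counts adjusted over the list alone (camera adjusted p = 0.381), with Kdr at 3.24 ± 0.31 and Wnt3a at -3.53 ± 0.38 (average log2 change ± SE). Of 17 definitive and foregut endoderm genes, 6 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.267). Of 24 primitive and visceral endoderm genes, 10 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.149), with Col4a2 at 1.07 ± 0.09 and Lama1 at -2.09 ± 0.14. Of 13 hepatocyte and gut epithelium genes, 6 rose and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 0.0980). Of 14 neuroectoderm genes, 4 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.983), with Sox11 at 1.72 ± 0.11 and Tubb3 at -2.48 ± 0.18. Of 17 neural crest genes, 4 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.322), with Msx1 at 4.27 ± 0.42, Sox9 at 3.19 ± 0.54 and Eya1 at -3.04 ± 0.27. Of 15 granulosa cell genes, 3 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.709), with Irx3 at 2.90 ± 0.52 and Rspo1 at 1.68 ± 0.20. Of 16 regulatory T cell genes, 7 rose and 1 fell (9 and 1 adjusted over the list alone; adjusted p = 0.0720), with Ikzf4 at 1.48 ± 0.20. Of 17 genes of the 2-cell-like state, 6 rose and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 0.0574), and Pramel7, which has near copies, fell by 2.68 ± 0.32. Of 20 germ cell and meiosis genes, 8 rose and 4 fell, also adjusted over the list alone (adjusted p = 0.296), with Ddx4 at 1.59 ± 0.12 and Stra8 at -3.23 ± 0.16. Of 17 fibroblast and smooth muscle genes, 8 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.0574), with S100a6 at 2.59 ± 0.22 and Vim at -1.31 ± 0.08.

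Among signalling, stress, metabolic and cell cycle lists, 9 of 17 Wnt targets rose and 2 fell, also adjusted over the list alone (adjusted p = 0.230), with Lef1 at 3.70 ± 0.59 and Nkd1 at 1.71 ± 0.21. Of 19 TGF-beta, Nodal and BMP targets, 6 rose and 3 fell (6 and 4 adjusted over the list alone; adjusted p = 0.252), with Id2 at 3.09 ± 0.22, Id3 at 2.02 ± 0.16 and Lefty1 at -1.87 ± 0.25. Of 18 p53 targets, 7 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.267), with Cdkn1a at -0.70 ± 0.14. Of 20 genes of the integrated stress and unfolded protein response, 3 rose and 7 fell, also adjusted over the list alone (adjusted p = 0.0720), with Psat1 at -1.10 ± 0.11. Of 21 cholesterol synthesis genes, none rose and 5 fell, also adjusted over the list alone (adjusted p = 0.0720), with Msmo1 at -0.87 ± 0.08. Of 21 glycolysis and hypoxia genes, none rose and 1 fell (none adjusted over the list alone; adjusted p = 0.530). Of 20 genes of the G2 and M phases, 4 rose and 3 fell (4 and 4 adjusted over the list alone; adjusted p = 0.983), with Cdc20 at 0.89 ± 0.10; camera put this list upward, while its median change was -0.09.

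Relative to the other lines, cholesterol synthesis genes had a higher change in iFoxG1 (camera adjusted p = 4.24e-07, and adjusted p = 0.0848 with an estimated correlation) and in iFoxP3 (camera adjusted p = 4.67e-05, and adjusted p = 0.197 with an estimated correlation). Since each line is compared with a mean that holds iFoxC1, where these genes fell, the 3 results are not separate.

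The first 3 principal components of the 17 libraries, over 10227 genes, held 39.7%, 16.9% and 16.4% of the variance. The deviation of a line from the other lines at 24 h, taken separately in each library set over the 10227 genes (not independent replicates), correlated between the sets with Pearson r of 0.660 for iFoxA1, 0.732 for iFoxC1, 0.706 for iFoxG1, 0.532 for iFoxP3 and 0.139 for iFoxL2. The replicate pairs of iFoxA1 within the first set had a chi-square per gene of 2.01 at 0 h and 2.81 at 24 h, where counting error alone gives 1. Pairs that span the sets lay between 52.7 (iFoxC1) and 234.6 (iFoxL2).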
